A study of Hordeum vulgare with 12 samples.

How the data were processed

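Small RNA libraries were made from total RNA of shoots and roots of 2-week-old barley (Hordeum vulgare) of the cultivar Golden Promise. Per the labels' protocols, plants were grown in perlite with a nutrient medium holding 28 mM NH4NO3 (control) or 280 mM NH4NO3 (nitrogen excess), and the libraries were prepared with the Illumina TruSeq small RNA kit. The labels give 4 groups of 3 biological replicates, which makes 12 libraries. Whether shoots and roots of one number came from the same plants is not given in the sources used here. Library names place replicate 1 of each group in one naming series (A), most other libraries in another (B), and the nitrogen-excess root replicate 3 alone in series C.

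The authors' deposited tables, one per tissue, list the same 3258 sequences of 17 to 28 nt, each with the plant miRNA names it carries. The deposited counts are whole numbers per sequence and library. The trimming, the counting tool and the mismatches allowed are not given in the sources used here. In the deposited signal columns, each normalized value equals its count divided by a factor shared by all sequences of a library, and DESeq2 is named in the submitters' processing notes without a version. The deposited log2 fold change and the deposited p-value columns, per the file headers, come from the same comparison of nitrogen excess with control. DESeq2 was therefore the authors' test, and their values are quoted only where named as such. Counting left traces in the values: in all 79 pairs where one listed sequence lies inside a longer one with at least 10 counts, the shorter sequence had 0 counts. The miR528-3p sequence and the entry OLAs_528, which overlap, differed by at most 3 counts in any library, with totals of 1679 and 1674. These entries share reads or stand for the same molecules and are not independent, and the same can hold for other near-identical family members.

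The totals over the listed sequences ranged from 245176 to 2246495 counts per library. They cover listed miRNA sequences only and are not the sequencing depth of the library. 2561 of the 3258 sequences had no count in any library. Wilson intervals at the 95% level are given for shares of a single library and cover counting error only, since reads without molecular identifiers are not independent molecules.

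The counts were analysed with edgeR 4.0.16 in R 4.3.3. Each tissue was fitted alone with condition as the term. Libraries were scaled by TMM, sequences with low counts were removed with filterByExpr (minimum count 10, minimum total 15), and the quasi-likelihood test was used with Benjamini-Hochberg adjustment at 0.05. Standard errors were derived from the fold change and the F statistic. The same model was fitted to counts summed per miRNA family, with families taken from the names. The difference between tissues was tested as the interaction of tissue and condition over all 12 libraries, on the 127 sequences kept in both tables. Levels are CPM values from edgeR after TMM scaling, given as mean ± SD. TMM was computed separately for each comparison, and separately for sequences and for families. Levels and changes of a family and of its sequences are therefore on different scales. Shares of length classes and of fragments were compared with a two-sided exact permutation test, for which 3 against 3 libraries cannot give a p below 0.1.

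Before the data were examined, 10 lists of miRNA families were fixed: phosphate, nitrogen-reported, sulfate, copper, phase and growth, leaf and root patterning, auxin signalling, small RNA machinery, phasiRNA triggers and NLR regulators, and cereal-enriched. They were tested with camera at a preset correlation of 0.01 (limma 3.58.1), with camera at an estimated correlation and with fry beside it, and lists under 3 measured members were not tested. The named sequences were fixed by a rule at the same time. Where fewer than 10 sequences were called in a tissue, the 10 with the smallest unadjusted p are named, whatever their direction. The 2 members with the highest mean level are named per list and tissue, and the 10 called families with the largest change. Had 10 or more been called, the 10 with the largest change per direction whose ranges do not overlap would have been named, with at most 2 per family. The 5 largest called differences between tissues would also have been named.

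The alternatives were DESeq2 size factors or equal totals in place of TMM, no filter or a filter of at least 20 counts in at least 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, the naming series as a term, series B alone, and leaving out each library. Alternatives planned for normalized values (pseudocounts, reads recovered from normalized values) were not run, because counts were deposited. The comparison of root with shoot in control plants, the fits without 2 libraries at once, the list tests with an estimated correlation or fry when single libraries were left out, the fits with the most abundant sequence removed or with each family's most abundant sequence, and the match to tRNA-Asp were chosen after the data had been seen. The labels call the replicates biological, and each library was counted as 1 on that ground. To look for a library deposited more than once, replicates of a group were compared by chi-square, which gave 274.0 to 2005.6 per degree of freedom. Such values exclude identical counts only and do not tell biological from technical spread.

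The count model was tested on simulated counts with the means, library sizes and dispersions of the real libraries. In shoot, over 148 sequences, it called 49.7% of sequences changed 8-fold and 86% of those changed 16-fold, and 0.5% of unchanged ones. In root, over 146 sequences, it called 7.7% at 8-fold and 34.5% at 16-fold. For families it called 69.9% at 8-fold among 57 families in shoot and 9.5% among 65 families in root. The interaction model called 27% of sequences given a 16-fold difference among 127. A copper list raised 4-fold was called by camera at the preset correlation in 100% of simulations in either tissue. The simulated sequences varied independently, so this does not show how the list test performs where members move together. The estimated correlation of the real copper list was 0.24 in shoot and 0.62 in root. Genomic positions of the miRNA loci were not analysed here.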

Results

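Small RNAs of barley shoots and roots were sequenced to ask how miRNA levels differ between plants given 28 mM NH4NO3 and plants given 280 mM, a nitrogen excess, at 2 weeks of age. Each of the 4 groups held 3 libraries. Total counts over the listed miRNA sequences were 1303233, 1215590 and 1236508 in control shoot, and 2246495, 779326 and 245176 in nitrogen-excess shoot. They were 1633631, 1148952 and 655033 in control root, and 451297, 1377990 and 1590461 in nitrogen-excess root. A single miR166 sequence (named hvu-miR166b) took from 43.62% (95% Wilson interval 43.55% to 43.68%) to 79.76% (79.70% to 79.82%) of the counts of a library. miR166 targets the HD-ZIP III transcription factors that pattern leaves and roots.

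The library labelled nitrogen-excess shoot replicate 3 and the library labelled control root replicate 3 stood apart from their tissues. On a scale on which the mean of the shoot libraries is 0 and that of the root libraries is 1, computed from 167 sequences with each library left out of the means it was placed against, the other 5 shoot libraries lay between -0.34 and 0.03 and the other 5 root libraries between 0.79 and 1.39. The library labelled nitrogen-excess shoot 3 lay at 1.04 and the library labelled control root 3 at -0.16. The sequence ppt-miR319c, chosen after its values were seen, had 505 counts in the library labelled nitrogen-excess shoot 3 against at most 36 in the other shoot libraries. It had 22 counts in the library labelled control root 3 against at least 470 in the other root libraries. All values use the labels as given unless a sentence says otherwise. Fold changes without these libraries are given for named sequences whose sign turned or whose value moved by over 1.5 times.

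**Figure D1:**
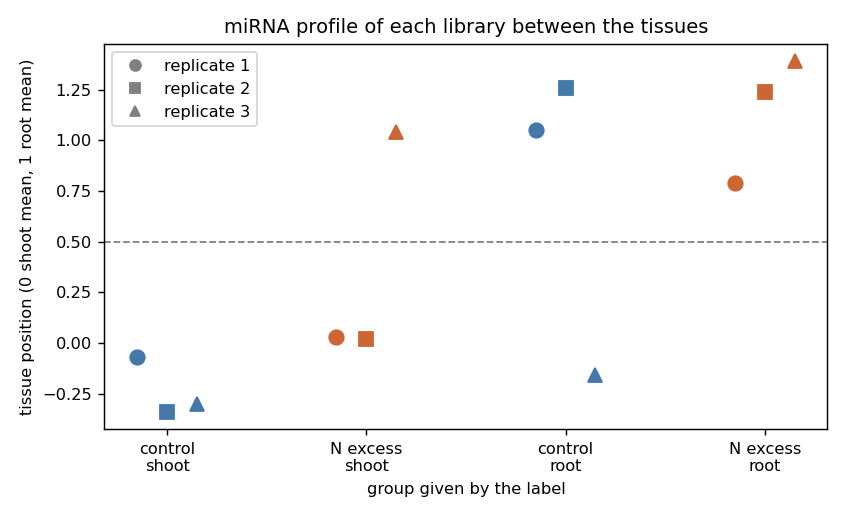
Position of each of the 12 libraries between the mean shoot profile (0) and the mean root profile (1), on the vertical axis with no unit, by the group its label gives on the horizontal axis; symbols mark replicate numbers, colours mark control (blue) and nitrogen excess (orange), and the dashed line is the midpoint. The triangle of nitrogen-excess shoot lies at 1.04 and the triangle of control root at -0.16, each on the other tissue's side.

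In shoot, 5 miRNA families were higher under nitrogen excess, and 4 of them are the copper miRNAs, which are induced when copper is short and repress copper proteins such as laccases, plantacyanins and superoxide dismutases. Both media held 8 µM CuSO4. miR398 rose from 39.8 ± 11.9 to 503 ± 598 CPM (SD, n = 3 each), a log2 fold change of 3.67 ± 0.92 (SE), and miR528 rose from 73.1 ± 27.3 to 783 ± 390 CPM, by 3.42 ± 0.83. miR397 rose from 439 ± 255 to 4378 ± 2815 CPM, by 3.32 ± 0.90, and miR408 from 189 ± 66.6 to 1290 ± 870 CPM, by 2.77 ± 0.84. The other called family was miR5054, at 3.18 ± 0.95. Adjusted p in edgeR's quasi-likelihood test was 0.0151 for miR398 and miR528, 0.0233 for miR397, and 0.0339 for miR408 and miR5054. In each of the 5 families all 3 nitrogen-excess libraries lay above all 3 controls. Family levels and changes cannot be compared directly with those of single sequences, which were scaled apart. In control shoot the miR397 family stood at 439 CPM and its member bdi-miR397b-5p, on the sequence scale, at 553 CPM. Of 57 families tested, none was called lower. The families miR6300 and miR8175, whose sequences lie within tRNA-Asp, stood at 2.68 ± 0.89 (adjusted p = 0.0558) and 2.83 ± 1.00 (adjusted p = 0.065) and were not called, with overlapping groups. Both were highest in the library labelled nitrogen-excess shoot 3, where the 4 copper families were lowest among the nitrogen-excess shoots, and without it stood at 1.18 and 1.17.

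These family calls were sensitive to scaling and to single libraries. Leaving out any 1 of the 6 libraries other than control shoot 1 gave 0 called families, leaving out control shoot 1 gave 9, and the naming series as a term gave 11. The median family moved by 0.60 on the log2 scale with TMM, and relative to that median the copper families stood at 2.17 to 3.06. With DESeq2 size factors or equal totals, 0 families were called, while the 4 copper families kept positive changes relative to the median (2.26 to 3.24 and 2.46 to 3.55). Without the library labelled nitrogen-excess shoot 3, 0 families were called: the copper families stood at 2.82 to 3.97 with adjusted p of 0.0598 to 0.0813. miR5054 stood at 1.07 ± 0.68 (adjusted p = 0.612). Much of the size of the copper change rested on nitrogen-excess shoot 1, which held the highest level of all 4 families (miR398 at 1191 CPM against 207 and 111). Without it miR398 stood at 1.28 ± 0.52, miR408 at 1.36 ± 0.63, miR397 at 2.03 ± 0.85 and miR528 at 2.35 ± 0.64 (adjusted p = 0.198, 0.198, 0.198 and 0.169), around a family median of 0.09. The level of miR5054 in the library labelled nitrogen-excess shoot 3 was 15099 CPM, against 2199 and 1488 in the others.

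**Figure D2:**
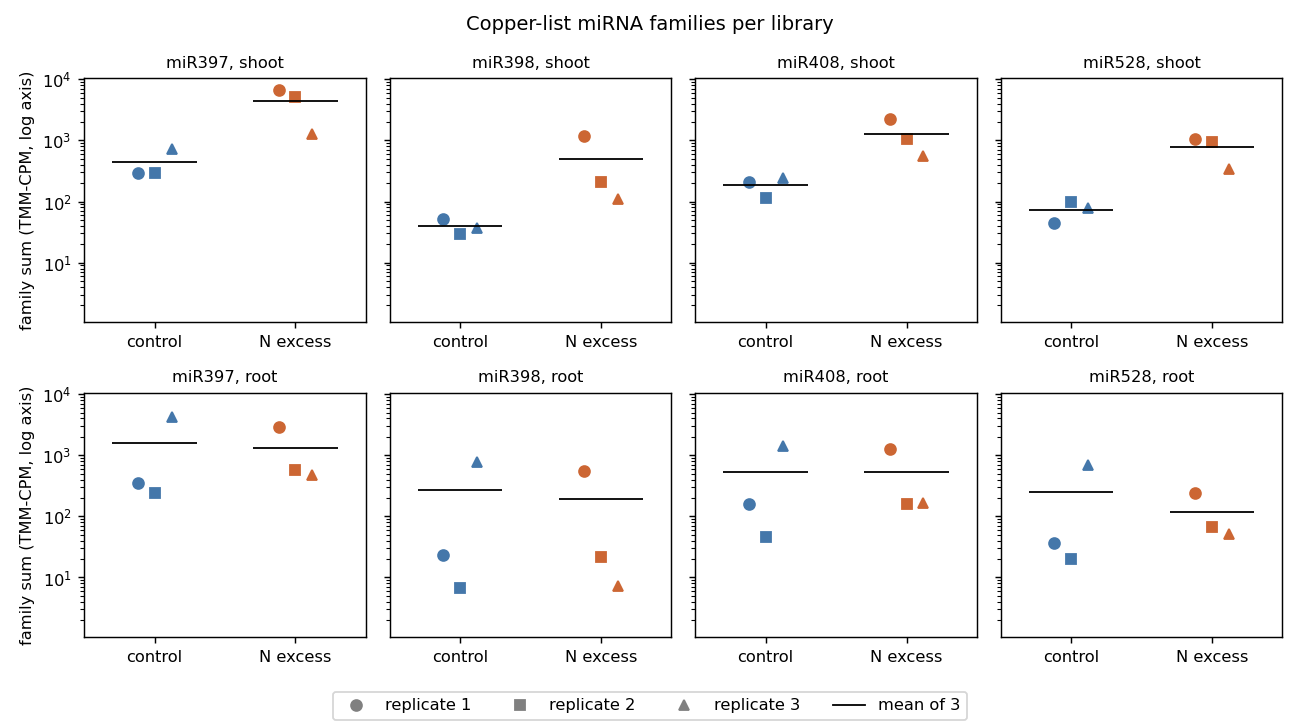
Level of 4 copper-list miRNA families per library (TMM-scaled CPM, log axis) in control (blue) and nitrogen excess (orange), shoot above and root below; symbols mark replicate numbers and horizontal lines the mean of 3 libraries. In shoot the 3 nitrogen-excess libraries lie above the 3 controls for each family; in root the triangle of control root, the library labelled control root 3, lies far above the other 2 controls. The tissues were scaled separately.

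At the level of single sequences, 0 of 148 were called in shoot (edgeR; lowest adjusted p = 0.085), 15 had an unadjusted p below 0.05 where 7.4 would be expected by chance, and DESeq2 on the same sequences called 8. The authors' deposited table has 6 shoot sequences with an adjusted p below 0.05: ata-miR408-5p, ata-miR528-3p, OLAs_528, ata-miR398g-3p, bdi-miR397b-5p and hvu-miR6186. The 10 sequences with the smallest p were led by ata-miR408-5p (CAGGGATGGAGCAGAGCAAGG), at 35.2 ± 18.8 CPM in control and 459 ± 139 CPM in nitrogen excess, a log2 fold change of 3.71 ± 0.91. ata-miR528-3p (CCTGTGCCTGCCTCTTCCATT) and its overlapping entry OLAs_528 stood at 3.33 and 3.32, ata-miR398g-3p (TGTGTTCTCAGGTCGCCCCCG) at 3.03 and bdi-miR397b-5p (ATTGAGTGCAGCGTTGATGAA) at 2.58. cme-miR395f, of a family that responds to sulfate shortage, stood at 2.36. In these 6 sequences all nitrogen-excess libraries lay above all controls. The remaining 4 were ppt-miR319c at 6.54, tae-miR319 at 5.05, ata-miR171a-3p at 3.23 and bdi-miR5054 at 2.73. Their high values came from the library labelled nitrogen-excess shoot 3, and without it they stood at 0.55, 0.62, 0.03 and 0.66. Other sequences of the miR528 and miR408 families changed less. ata-miR528-5p stood at 2.14, ppt-miR408b at 2.03 and tae-miR408 at 1.34, so the changes of ata-miR528-3p and ata-miR408-5p do not hold for each sequence of their families. The groups overlapped for ppt-miR408b and tae-miR408 but not for ata-miR528-5p. Statements on targets refer to families, and which arm (5p or 3p) acts on the targets was not examined here. Over all 148 sequences, 20 (13.5%) had groups with no overlap, against 10% expected by chance.

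As a list, the copper miRNAs were higher in nitrogen-excess shoot. All 9 measured members had positive changes, with a median log2 fold change of 2.58 and a mean of 2.63. None was called over all sequences and 6 were called when adjusted over the list alone. The 9 include ata-miR528-3p and OLAs_528, which hold nearly the same reads. They count as separate members in these numbers and in the list tests. Camera gave an adjusted p of 3.75e-10, and the call was lost with an estimated correlation (adjusted p = 0.114 with an estimated correlation) and with fry (adjusted p = 0.073). The 2 most abundant members were bdi-miR397b-5p (553 ± 345 against 3316 ± 2145 CPM) and tae-miR408 (178 ± 82.2 against 449 ± 431 CPM, log2 fold change 1.34 ± 0.90). Without the library labelled nitrogen-excess shoot 3, camera's adjusted p was 4.12e-14 and the median 2.99, and the call was again lost with an estimated correlation (adjusted p = 0.0896) and with fry (adjusted p = 0.0731). Without nitrogen-excess shoot 1 the median was 2.27 with 8 of 9 members positive (camera adjusted p = 2.72e-05; 0.149 with an estimated correlation, 0.00441 with fry).

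None of the other 9 lists was called in shoot. Of the 3 sulfate members, all of family miR395, 3 were positive (median 1.81, camera adjusted p = 0.0913), and 1 was called when adjusted over the list alone. gma-miR395h stood at 0.82 ± 1.00. Without the library labelled nitrogen-excess shoot 3, the sulfate list was called (camera adjusted p = 0.00156, and 0.337 with an estimated correlation). It was also called without control shoot 1, with a median of 2.92 (camera adjusted p = 0.00731, and 0.414 with an estimated correlation). The 4 phosphate members (miR399 and miR827, which act in phosphate uptake and storage) were all positive, with a median of 1.02 and an adjusted p of 0.189. Their most abundant members were bdi-miR827-5p at 0.79 ± 0.85 and bdi-miR827-3p at 0.13 ± 0.79.

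Lists of growth regulators gave no call in shoot. Of 35 nitrogen-reported members, 14 were positive and 21 negative (median -0.13, adjusted p = 0.304). ata-miR167d-5p, which targets auxin response factors, was at 22047 ± 2784 CPM in control and 11733 ± 1402 in nitrogen excess, with no overlap of the groups (log2 fold change -0.91 ± 0.68, adjusted p = 0.597). osa-miR444b.1, of a monocot family that targets MADS-box genes in nitrate signalling, stood at -0.21 ± 0.77. Auxin signalling held 16 members with a median of -0.23 (adjusted p = 0.189); ata-miR167f-5p stood at -0.13 ± 0.73. Phase and growth held 33 members, with a median of -0.27 and a mean of 0.05, with camera's direction down (adjusted p = 0.189). 2 of them, ppt-miR319c and tae-miR319, were called when adjusted over the list alone; hvu-miR159b stood at -0.27 ± 0.90 and ata-miR396c-5p, which targets growth-regulating factors, at -1.31 ± 0.72. Leaf and root patterning held 26 members with a median of -0.20 (adjusted p = 0.189); hvu-miR166b stood at 0.40 ± 0.52 and bdi-miR166h-3p at -0.53 ± 0.74. The 4 small RNA machinery members, all miR168, which targets ARGONAUTE1, had a median of -0.36 (adjusted p = 0.633), with hvu-miR168-5p at 0.02 ± 0.60 and hvu-miR168-3p at -0.45 ± 1.04. The 4 phasiRNA triggers and NLR regulators had a median of -0.36 (adjusted p = 0.287), with hvu-miR5048b at -0.13 ± 0.69 and ata-miR390-5p, the trigger of tasiRNAs from TAS3, at 783 ± 15.5 against 267 ± 53.1 CPM (-1.55 ± 0.81, adjusted p = 0.443). The 16 cereal-enriched members had a median of -0.08 and a mean of 0.53, with camera's direction up (adjusted p = 0.287), and 2 of them, the miR528-3p pair, were called when adjusted over the list alone. With the library labelled nitrogen-excess shoot 3 left out, osa-miR444b.1 moved to -1.24, and signs turned for bdi-miR827-3p (-0.18), hvu-miR159b (0.23), hvu-miR166b (-0.01) and hvu-miR5048b (0.17). Camera's direction for small RNA machinery turned to up (adjusted p = 0.866), as it did when control shoot 1 was left out instead (adjusted p = 0.554).

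In root, no miRNA was called. Of 146 sequences, 0 were called by edgeR (lowest adjusted p = 0.955), 1 had an unadjusted p below 0.05 where 7.3 would be expected, and DESeq2 called 0, as did the authors' deposited table. Of 65 families, 0 were called, and 0 had an unadjusted p below 0.05. The spread between root libraries was wide, with a biological coefficient of variation of 0.888 against 0.724 in shoot. The 10 sequences with the smallest p included bdi-miR169k-3p (9.63 ± 11 against 82.4 ± 56.3 CPM, log2 fold change 3.15 ± 1.19) and ata-miR169f-3p (94.3 ± 11.7 against 318 ± 131 CPM, 1.75 ± 0.87). Both belong to a family that targets NF-YA transcription factors, though whether these 3p sequences act on those targets was not examined here. bdi-miR827-5p stood at 2.00 ± 1.04, osa-miR399d at 2.00 ± 1.06, ata-miR399b-3p at 2.71 ± 1.43 and ata-miR164c-3p at 1.96 ± 1.03. gma-miR396e stood at 1.79, ata-miR396e-3p at 1.82, tae-miR9774 at -2.64 and hvu-miR171-3p at -1.68. The value of tae-miR9774 came from the library labelled control root 3 (632 CPM against 65.1 and 25.7 in the other controls), and without it was -0.24. Without it bdi-miR827-5p stood at 3.53, osa-miR399d at 2.97 and ata-miR399b-3p at 4.45. Without the library labelled control root 3, 11 sequences had an unadjusted p below 0.05, and 1 family was called: miR827, at 3.62 ± 1.04 (adjusted p = 0.0419).

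The phosphate list was the only list called in root. Its 4 members had a median log2 fold change of 2.00 and a mean of 1.91 (camera adjusted p = 0.00207), and the call was lost with an estimated correlation (adjusted p = 0.822 with an estimated correlation). None was called over all sequences or when adjusted over the list alone. The call was also lost without control root 1 (adjusted p = 0.246) or control root 2 (0.293), and without nitrogen-excess root 3 the median was 0.78 (camera adjusted p = 0.0184; 0.915 with an estimated correlation). Without the library labelled control root 3 the adjusted p was 3.63e-06 (0.622 with an estimated correlation) and the median 3.27.

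The 9 copper members in root had a median of -0.40 and a mean of -0.20, while camera's direction was up (adjusted p = 0.931). bdi-miR397b-5p stood at -0.20 ± 1.15 and tae-miR408 at -1.19 ± 1.31. Without nitrogen-excess root 1 the median was -2.04, with 1 of 9 members positive (camera adjusted p = 0.313). The values over all libraries also turn on the library labelled control root 3, in which miR397 was at 4186 CPM against 353 and 243 in the other controls. Without it bdi-miR397b-5p stood at 1.88 and tae-miR408 at 1.31, the median was 1.88, and the list was called higher (camera adjusted p = 0.00068; 0.665 with an estimated correlation). Leaf and root patterning (24 members, median -0.52, adjusted p = 0.292) was called lower without that library (0.0301; 0.665 with an estimated correlation). hvu-miR166b stood at -0.73 ± 0.92 and bdi-miR166h-3p at -0.90 ± 1.06, the latter at -0.17 without that library.

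The remaining 7 lists were not called in root. Sulfate had 3 members with a median of 1.09 (adjusted p = 0.432), with gma-miR395h at 1.09 ± 0.97 and cme-miR395f at 1.16 ± 0.98. Nitrogen-reported had 32 members with a median of -0.04, a mean of 0.32 and camera's direction up (0.292); osa-miR444b.1 stood at -0.17 ± 0.77 and ata-miR167d-5p at -0.62 ± 0.81. Phase and growth had 27 members with a median of -0.53 (0.292), with hvu-miR159b at 0.07 ± 0.79 and bdi-miR319b-3p at -0.16 ± 0.94. Auxin signalling had 14 members with a median of -0.04 (0.931), with ata-miR167f-5p at -0.06 ± 0.98. Small RNA machinery had 4 members with a median of 0.43 (0.432), with hvu-miR168-5p at 0.22 ± 0.83 and osa-miR168b at 0.19 ± 0.99. The 5 phasiRNA triggers and NLR regulators had a median of -0.11, a mean of 0.01 and camera's direction up (0.931), with hvu-miR5048b at -0.11 ± 0.79 and tae-miR5048-5p at -0.37 ± 0.87. The 19 cereal-enriched members had a median of -0.27 (0.948). The adjusted p-values are camera's. Signs turned without the library labelled control root 3 for hvu-miR159b (-0.13), ata-miR167f-5p (1.07), hvu-miR168-5p (-0.17) and osa-miR168b (-0.26). Camera's direction turned to up for auxin signalling and cereal-enriched miRNAs (adjusted p = 0.915 for each).

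Whether the response differed between shoot and root was tested as an interaction. Of 127 sequences, 0 were called (edgeR; lowest adjusted p = 0.929), and 4 had an unadjusted p below 0.05 where 6.4 would be expected. The copper calls in shoot were made on families and on a list, for which no interaction was tested. Those calls and their absence in root are not shown to differ. The smallest p values were those of the miR528 sequences, led by ata-miR528-5p, chosen after its values were seen, at a root minus shoot difference of -3.72 ± 1.43. Without both libraries that lay nearer the other tissue, that difference shrank to -1.63 ± 1.09 and that of ata-miR528-3p from -4.17 to -1.19. The smallest p values were then those of bdi-miR827-3p (3.30 ± 1.18) and bdi-miR827-5p (3.12 ± 1.25), and 0 were called (edgeR; lowest adjusted p = 0.832), with 4 at an unadjusted p below 0.05.

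In shoot, 21-nt sequences made up 90.5% ± 0.187 (SD, n = 3) of the counts in control and 90.9% ± 1.05 in nitrogen excess (exact permutation test, p = 0.7). 22-nt sequences made up 8.20% ± 0.137 in control and 5.81% ± 1.61 in nitrogen excess, with no overlap of the groups (exact permutation test, p = 0.1, the smallest possible); the nitrogen-excess libraries held 6.77%, 6.72% and, in the library labelled nitrogen-excess shoot 3, 3.95%. 24-nt sequences made up 0.195% ± 0.024 and 0.115% ± 0.132 (p = 0.4, exact permutation test). In root, the 21-nt share was 87.4% ± 8.31 and 85.8% ± 5.70 (exact permutation test, p = 0.8), the 22-nt share 4.12% ± 3.49 and 3.88% ± 1.62 (exact permutation test, p = 1.0), and the 24-nt share 0.072% ± 0.1 and 0.022% ± 0.008 (exact permutation test, p = 0.9). The higher control means of the 22-nt and 24-nt shares came from the library labelled control root 3, at 8.14% and 0.187%. The other control roots held 2.22% and 1.99% of 22 nt, below the nitrogen-excess roots (2.77%, 3.12% and 5.74%), and 0.015% and 0.013% of 24 nt (0.029%, 0.013% and 0.023% in nitrogen excess). The counts cover listed miRNAs, so the 24-nt class here is not the siRNA class. No listed sequence was named as rRNA, tRNA or snoRNA, or from the animal species searched for. By sequence, only a single tRNA-Asp was searched, and no other tRNA or rRNA, so further fragments can be among the listed sequences. 3 listed sequences, gma-miR6300, OLAs_miR6300 and ath-miR8175, lie within tRNA-Asp. They made up 7.22% ± 9.71 of counts in control root and 7.22% ± 6.5 in nitrogen-excess root (exact permutation test, p = 1.0). In control shoot they made up 0.367% ± 0.251, and in nitrogen-excess shoot 1.37% ± 1.17 (exact permutation test, p = 0.1, the smallest possible). Nitrogen-excess shoots 1 and 2 had 0.682% and 0.706%, barely above control shoot 1 (0.654%). The highest share was 18.3% (Wilson interval 18.25% to 18.39%) in control root 2. Control root 1 had 3.01%, the library labelled control root 3 had 0.336%, and the library labelled nitrogen-excess shoot 3 had 2.72%. The miR5054 sequence made up 0.218% ± 0.124 in control root and 0.934% ± 0.508 in nitrogen-excess root (exact permutation test, p = 0.1, the smallest possible). In shoot it made up 0.09% ± 0.014 and 0.48% ± 0.553 (exact permutation test, p = 0.3).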

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

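The tissue comparison in control plants, the removal of the top miR166 sequence and the use of each family's most abundant sequence were chosen after the data had been seen, as were the estimated correlation and fry with single libraries left out. In root, 0 sequences were called under every alternative run, and so were 0 differences between tissues; with few libraries and a wide spread this says little about stability. In shoot, 0 sequences were called with TMM and edgeR, 8 without a filter, 8 with DESeq2, 1 with limma-voom, 5 without the top miR166 sequence, and 0 to 2 when each library was left out. Those 1 or 2 were miR319 sequences, high in the library labelled nitrogen-excess shoot 3. The 5 shoot families became 0 with DESeq2 size factors, equal totals, the stricter filter, series B alone or each family's most abundant sequence, and 11 with the naming series as a term. They became 4 without a filter (miR397, miR398, miR528 and miR6210), 4 with DESeq2 (miR397, miR408, miR5054 and miR528) and 4 with limma-voom (miR397, miR398, miR408 and miR528). They became 0 to 9 when each library was left out: 9 without control shoot 1, and 0 without any other library. All of these calls were upward. The cause was not tested, except that fewer libraries enter the leave-one-out and series B fits. The same-number correlations of deviations were 0.50, 0.06 and 0.05 in shoot and 0.15, 0.50 and -0.24 in root. Shoot control 1 and root control 2 correlated best with their own number, and the other controls did not. The deviations were taken from group means that include the libraries nearer the other tissue, so the check cannot settle whether shared numbers are pairs. A shared origin of single pairs is not excluded. With the replicate block, 3 shoot sequences, 6 shoot families and 0 root sequences were called.

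The copper call in shoot (1 list) became 0 with an estimated correlation (adjusted p = 0.114) and with fry (0.073), and 1 to 2 lists were called when each library was left out, with an adjusted p for copper of 4.12e-14 to 2.72e-05 (0.0896 to 0.405 with an estimated correlation, 0.00441 to 0.262 with fry). The phosphate call in root (1 list) became 0 with an estimated correlation (0.822), with fry (0.81) and with family sums, where the list has too few families to be tested. Between 0 and 3 root lists were called when each library was left out, with an adjusted p for phosphate of 3.63e-06 to 0.293 (0.622 to 0.922 with an estimated correlation, 0.442 to 0.881 with fry). Leaving out each library gave 0 to 1 root families. The tissue comparison in control plants called 0 sequences, 20 without a filter, 16 with DESeq2, and 0 to 35 when each library was left out. Counted as distinct sequences, the difference of nitrogen excess from control was -1.45 percentage points for 21 nt and -0.963 for 24 nt in shoot, and 1.887 for 24 nt in root. Matching fragments by exact name left none to compare. The pseudocount alternatives did not apply to counts.

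Uncalled sequences with small changes turned sign under some settings. In shoot, hvu-miR159b gave 0.01 with equal totals, 0.05 without a filter, 0.08 with the stricter filter, 0.20 with limma-voom, 0.32 with the series term and 0.82 in series B. hvu-miR168-3p gave 0.90 with limma-voom, 0.77 with the block, 0.71 with the series term and 1.82 in series B. hvu-miR168-5p gave -0.04 with equal totals and -0.04 with the block. hvu-miR5048b gave 0.02 with DESeq2 size factors or DESeq2 and 0.17 in series B, and ata-miR167f-5p 0.06 in series B. In root, bdi-miR397b-5p gave 0.28 with limma-voom, 0.68 with the block and 0.48 with the series term, and tae-miR408 gave 0.33 with the block. bdi-miR319b-3p gave 0.08 with DESeq2 size factors or DESeq2, 0.70 with equal totals, 0.22 with limma-voom and 0.20 with the block. osa-miR444b.1 gave 0.06 with equal totals and 0.05 in series B, hvu-miR5048b 0.20 and 0.12, and tae-miR5048-5p 0.27 with equal totals. With the series term and in series B, hvu-miR159b gave -0.29 and -0.63 and ata-miR167f-5p 0.23 and 0.32. In series B, ata-miR167d-5p gave 0.05 and hvu-miR166b 0.13. When each library was left out, the shoot ranges that crossed 0 were -0.18 to 0.47 (bdi-miR827-3p), -1.24 to 0.17 (osa-miR444b.1), -1.01 to 1.56 (hvu-miR159b), -0.01 to 0.74 (hvu-miR166b), -0.68 to 0.13 (ata-miR167f-5p), -0.15 to 0.31 (hvu-miR168-5p), -0.97 to 2.36 (hvu-miR168-3p) and -0.71 to 0.17 (hvu-miR5048b). In root they were -0.32 to 0.05 (osa-miR444b.1), -1.55 to 1.88 (bdi-miR397b-5p), -2.62 to 1.31 (tae-miR408), -0.13 to 0.37 (hvu-miR159b), -0.58 to 1.14 (bdi-miR319b-3p), -1.07 to 1.07 (ata-miR167f-5p), -0.17 to 0.66 (hvu-miR168-5p), -0.26 to 1.14 (osa-miR168b), -0.45 to 0.23 (hvu-miR5048b) and -0.75 to 0.08 (tae-miR5048-5p).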

Other observations

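The tests in this part were chosen after the results were seen, except the thinning to equal totals over the listed sequences and the counts over other splits of the libraries. Control root was compared with control shoot. With all 6 control libraries 0 of 144 sequences were called by edgeR (lowest adjusted p = 0.121), 18 had an unadjusted p below 0.05, and DESeq2 called 16. Without that library 35 were called, 21 higher and 14 lower in root, with 2 root libraries assumed to vary like the 3 shoot libraries. That library was left out because it lay on the shoot side of the tissue scale, a choice that by itself raises the count, so neither 35 nor the p-values are a fair test of the tissue difference. miR319, which targets TCP transcription factors, led: ppt-miR319c was at 1085 ± 293 CPM in root and 5.87 ± 1.27 CPM in shoot (log2 fold change 7.51 ± 0.70, adjusted p = 0.000372), and tae-miR319 was higher by 7.16 ± 0.69. ata-miR171a-3p, which targets GRAS transcription factors, was higher in root by 6.00 ± 0.71, and hvu-miR166b by 2.38 ± 0.32. bdi-miR160e-5p, which targets auxin response factors, fell by 3.83 on the log2 scale in root relative to shoot, and ata-miR396c-5p fell by 2.72. The tRNA-Asp sequence gma-miR6300 was higher in root by 7.17 ± 1.17. These sequences were chosen after their values were seen.

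The copper miRNAs higher in nitrogen-excess shoot are the first pattern weighed. The median log2 fold change of the 9 members was 2.58 over all 6 libraries. It was 2.99 without the library labelled nitrogen-excess shoot 3, 2.64 with the top miR166 sequence removed and libraries scaled to the remaining total (a test that replaced one by total scaling alone, which gave 2.66), and 3.28 with only the most abundant sequence of each of 4 families. The library labelled nitrogen-excess shoot 3 held the lowest level of all 4 families among the nitrogen-excess shoots. Leaving it out could therefore be foreseen to raise the median. The value of 2.99 shows only that this library did not produce the change, and an exchange of labels was not tested here. Without nitrogen-excess shoot 1 the median was 2.27, and the families stood at 1.28 to 2.35. The values of 2.64 and 2.66 argue against the scaling by abundant sequences as the cause of most of the change in that median. Reads shared between near-identical sequences stay open, because the most abundant sequence of a family can also hold shared reads. The value of 3.28 also came from a fit whose overall median was 0.23, against -0.07 over all sequences. Both media held 8 µM CuSO4. Whether copper availability in the plants fell under 280 mM NH4NO3 was not measured, and a lower copper supply to shoots stays an untested hypothesis. Other effects of 280 mM NH4NO3 that could raise these families were not tested either. The nitrogen-reported list did not hold these 4 families, so its result does not bear on them.

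Of the 10 splits of the 6 shoot libraries, 1 gave 5 families or more, the real one, and the highest other split gave 2. For lists, 6 splits in shoot gave 1 or more (real 1, highest other 2), and 6 in root gave 1 or more (real 1, highest other 3). 10 splits are too few for a share under 0.05. Where the real count was 0, every split reaches it, so the count says nothing about chance. This holds for all 10 splits for shoot sequences (highest other 2), root sequences (highest other 0), root families (highest other 0) and control tissues (highest other 0), and for all 100 drawn for the difference between tissues (highest other 4).

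The second pattern is the pair of libraries that lie nearer the other tissue. After every library was thinned to 245176 counts, the highest position of the other 5 shoot libraries was 0.09. The lowest position of the other 5 root libraries was 0.79. These values argue against a low total over the listed sequences as the cause, while sequencing depth itself was not matched. Unthinned, the other 2 nitrogen-excess shoot libraries lay at 0.03 and 0.02, above the control shoots (-0.07, -0.34 and -0.30), so a small shift of nitrogen-excess shoots towards root stays open, while a shift past the midpoint is argued against. For an exchange of labels, each library had to take the other tissue's side at over 80% of 35 tissue sequences chosen without them; the library labelled control root 3 did so at all 35, but the library labelled nitrogen-excess shoot 3 at 24 (68.6%), so by the bar as set the exchange failed. It was first read as argued against, and only after the value was seen was it read as open, because nitrogen-excess root 1 (74.3%) missed the bar as well; the bar was not moved, and 68.6% is still below all 3 nitrogen-excess root libraries (74.3%, 91.4% and 82.9%). miR397, chosen after its values were seen, had 5476 of 655033 counts in the library labelled control root 3. Nitrogen-excess shoots 1 and 2 had 17325 of 2246495 and 2080 of 779326. Control shoots had lower shares (468 of 1303233, 452 of 1215590 and 1315 of 1236508). The library labelled nitrogen-excess shoot 3 had 232 of 245176. That is a higher share than in control roots 1 and 2 (375 of 1633631 and 146 of 1148952). The nitrogen-excess roots had 1287 of 451297, 655 of 1377990 and 1378 of 1590461. The high share of the library labelled control root 3 goes with an exchange. The share of the library labelled nitrogen-excess shoot 3 lies above the control roots that an exchange would match. It lies within the range of the nitrogen-excess roots, so it does not speak against a root library. The names of the 2 libraries are consecutive within naming series B, which goes with an exchange but does not show one. An exchange, a mixed sample and another altered sample remain possible.

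The third pattern is the phosphate list in root, with a median of 2.00 over all 6 libraries. Without the library labelled control root 3 the median was 3.27. This rise could be foreseen, because that library held the highest control levels of miR827 (928 CPM) and miR399 (169 CPM). The value shows only that its inclusion did not produce the change, and an exchange of labels was not tested here. Without nitrogen-excess root 3, the sole library of its naming series, the median was 0.78, so much of the size of the change rests on nitrogen-excess root 3. The camera adjusted p of the list was then 0.0184, lost with an estimated correlation (adjusted p = 0.915), and a series difference may account for part of the change. An effect of nitrogen excess on phosphate signalling in root stays open and was not tested.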
